A study of Homo sapiens with 4 samples.

How the data were processed

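RNA was sequenced from NSC-34, a mouse motor-neuron-like hybrid cell line, in 4 libraries that form 4 groups of 1 library each. Cells carried either a negative-control lentivirus (LV-Ctrl) or a lentivirus for PGC-1α overexpression (LV-PGC-1a), and each kind of cell was sequenced without lipopolysaccharide (LPS) and after LPS for 6 h. The labels state an LPS dose of 1 mg/ml, which was taken over unchecked. Groups were taken from the sample labels. Per the labels' protocols, libraries were made from total RNA by fragmentation, random-primed first-strand synthesis and a dUTP-based second strand, and were sequenced on an Illumina HiSeq instrument.

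The values were taken as FPKM that the authors deposited per transcript, but no label or file header states the unit. StringTie is among the tools in the submitters' processing notes, which also list cutadapt, HISAT2 2.0.5, STAR 2.5.2b and the human build hg19 without saying which made these tables. If the values were TPM instead, they would differ from FPKM by a single factor per library, which changes the weight of the pseudocount and of the filter. Scaling each library to a total of 1000000 was therefore added as an alternative, and most counts depended on it. The labels give the organism as human, whereas all 26151 row identifiers carry the Ensembl prefix of mouse transcripts, so hg19 was not taken as the build of these rows. The highest of the 4 values of a row was never below 0.50024, so rows with lower values had apparently been removed before deposit. The deposited table with 2 libraries held the same 26151 rows, and 100% of its values equalled those of the table with 4 libraries, so only the latter was used.

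The low values showed no steps that single reads would leave, so the depth of the libraries is unknown and no interval or detection limit that needs it is given. A value of exactly 0 was found in at least 1 library for 4973 rows. Such a 0 can be a failed estimate or reads assigned to another transcript of the same gene, so these values are described as listed at 0.

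Values were compared as log2(value + 1), a scale that understates the change of low transcripts. The 22045 transcripts with a value of at least 1 in at least 1 library entered the comparisons, and a transcript was counted as higher or lower where the ratio on this scale was 2-fold or more. With 1 library per group no ratio of libraries has a replicate check, so the planned comparisons have no test, p-value or SD between replicates. The ratio of the vector libraries was taken without LPS and with LPS, and the ratio for LPS in LV-Ctrl and in LV-PGC-1a cells. The 2 vector ratios share no library, nor do the 2 LPS ratios. Counts shared by 2 ratios were set beside the number expected of independent lists (n1 × n2 / N), and correlations were taken across transcripts, which are not independent replicates. LPS changes that went the other way with the vector use the LV-Ctrl + LPS library in both ratios, and were set beside 100 simulated sets of unchanged libraries, with noise drawn within 20 bins of the mean from the difference of differences. Transcripts whose libraries of one side both lay 2-fold or more above both libraries of the other side are called separated. They were counted for the grouping by vector, the grouping by LPS and the grouping that follows neither (LV-Ctrl and LV-PGC-1a + LPS against the other 2), which serves as a background measured the same way. It equals the interaction of vector and LPS, so it also holds any real interaction.

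The comparisons, the rule for named features and most alternatives were set before the data were examined. The rule took, for the vector and for LPS, the 10 transcripts per direction with the largest value of the smaller of the 2 absolute log2 ratios, among those that moved the same way in both pairs. The files do not pair the identifiers with gene names, and 0 of them matched the gene tables used here, which are human. Values were therefore kept per transcript and not summed per gene, 26 planned gene lists including PGC-1α itself were not analysed here, and the parts of the rule that name genes by list or by interaction were not applied. Of each 10, only the first identifier is printed, with the range of the smaller log2 ratio over the 10.

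Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5, scaling by median ratio, scaling to the same total and a 3-fold threshold. Quantile normalization, scaling to a total of 1000000, leaving out transcripts with a value of 0, the separated counts, the counts of transcripts present on one side alone, rank correlations at high values and simulated noise scaled per library were added after the data were seen. So was a fit of vector and LPS without interaction by limma 3.58.1 in R 4.3.3, with a trend of variance on the mean and Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom, which is the interaction, so a real interaction enters its error. The counting was tested on simulated libraries of 22045 transcripts for the vector in both pairs, with 50 transcripts set higher per fold size. These were drawn only from transcripts with a mean of at least 5, and the fold was set on value + 1. Of them, the counting recovered 16% at 2-fold, 82% at 4-fold, 98% at 8-fold and 100% at 16-fold. The set 2-fold equals the threshold, so noise puts many of these transcripts under it and their recovery stays low. Recovery of transcripts with a lower mean was not tested. The test used 1 simulated set with equal noise. Such noise gave a mean of 4013 2-fold transcripts for the vector with LPS, against 2964 observed. Besides the set transcripts, 181 unchanged transcripts were called higher in both pairs. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.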

Results

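The data are transcript abundances of NSC-34 cells, a mouse motor-neuron-like hybrid line, in 4 groups of 1 library each: LV-Ctrl, LV-PGC-1a, LV-Ctrl + LPS and LV-PGC-1a + LPS. PGC-1α is a transcriptional coactivator known for its part in mitochondrial biogenesis, and LPS is a bacterial cell-wall component that activates Toll-like receptor 4. The series addresses PGC-1α in neurons in experimental autoimmune encephalomyelitis. With no replicate libraries, every difference below is a difference between libraries and has no replicate error. Rows are transcripts without gene names, so the level of the PGC-1α transcript itself could not be given and the vector labels were not checked.

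The tables held 26151 transcripts. A value of at least 1 was found for 17555 transcripts in LV-Ctrl, 18291 in LV-PGC-1a, 16983 in LV-Ctrl + LPS and 17207 in LV-PGC-1a + LPS. Median values were 2.41, 2.69, 2.17 and 2.27 in the same order, and the summed values were 368229, 338964, 347165 and 352166. LV-PGC-1a had the fewest transcripts at 100 or more, 461 against 589 in LV-Ctrl, 553 in LV-Ctrl + LPS and 571 in LV-PGC-1a + LPS. Its 10 most abundant transcripts took 5.91% of the summed values, against 4.15% in LV-Ctrl, 4.99% in LV-Ctrl + LPS and 5.29% in LV-PGC-1a + LPS. Transcripts listed at 0 numbered 1793, 2089, 2230 and 2470.

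The 2 LPS libraries were the most alike of the 6 pairs of libraries. Over 22045 transcripts, the correlation of their log2 values was 0.909 and the SD of their log2 ratios 0.781. LV-PGC-1a and LV-Ctrl + LPS were the least alike, with a correlation of 0.827 and an SD of 1.05. LV-Ctrl correlated at 0.856 with LV-PGC-1a, at 0.870 with LV-Ctrl + LPS and at 0.866 with LV-PGC-1a + LPS.

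The first comparison asks which transcripts differed with the PGC-1α vector. Without LPS, 2678 transcripts were 2-fold or more higher and 2287 lower in LV-PGC-1a than in LV-Ctrl, which is 22.5% of the transcripts compared. With LPS, 1517 were higher and 1447 lower, or 13.4%. Only a small part differed the same way in both pairs: 275 transcripts were higher in both, where 184.3 would be expected of independent lists, and 271 were lower in both, where 150.1 would be expected. These 546 transcripts did not exceed what unchanged libraries gave with simulated noise scaled per library, a mean of 554 and a range of 492 to 614, although equal noise gave a mean of 406 and a range of 351 to 453. Neither simulation settles the comparison, since they gave means of 4102 and 4013 2-fold transcripts for the vector with LPS, against 2964 observed. Noise in both was drawn from the difference of differences, so it holds any real interaction of vector and LPS. The noise scaled per library also takes every difference between libraries as noise, so it holds any effect of the vector or of LPS. Transcripts that went opposite ways were also more than expected, with 224 higher without LPS and lower with it (175.8 expected) and 226 the reverse (157.4 expected). Across transcripts the 2 log2 ratios were hardly correlated (Pearson's r 0.04, Spearman's rho 0.05). Between LPS-free libraries, the balance of higher and lower depended on abundance: among transcripts with a mean of at least 5, 875 were higher and 933 lower. With LPS it turned under median-ratio scaling, to 1465 higher and 1530 lower, under quantile normalization, to 1489 and 1540, and at a total of 1000000, to 2656 and 2696.

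The vector separated 395 transcripts, 196 with both LV-PGC-1a libraries 2-fold or more above both LV-Ctrl libraries and 199 with both below. The grouping that follows neither vector nor LPS separated 309, so the count for the vector was 1.28 times this background. The excess lay among transcripts with a mean under 20, and not only among those under 5. Under a mean of 5 the vector separated 277 and the background grouping 221, and from 5 to 20 they separated 108 and 71. Of the 2988 transcripts with a mean from 20 to 100, the vector separated 9 and the background grouping 17. Of the 525 transcripts with a mean of 100 or more, the vector separated 1 and the background grouping 0. The transcript ranked first among those higher with the vector, ENSMUST00000050872.14, had a value of 25.0 in LV-PGC-1a and 14.3 in LV-PGC-1a + LPS, against 0.00113 in LV-Ctrl and 0.000958 in LV-Ctrl + LPS. Its log2 ratios were 4.70 without LPS and 3.93 with it. Ranked first among those lower, ENSMUST00000167764.1 had 57.4 in LV-Ctrl and 33.9 in LV-Ctrl + LPS, and was listed at 0 in both LV-PGC-1a libraries. Over the 10 highest-ranked transcripts, the smaller log2 ratio lay between 3.17 and 3.93 for those higher, of which 3 were listed at 0 in both LV-Ctrl libraries. For the 10 lower ones its size lay between 3.22 and 5.12, and 5 were listed at 0 in both LV-PGC-1a libraries.

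**Figure D1:**
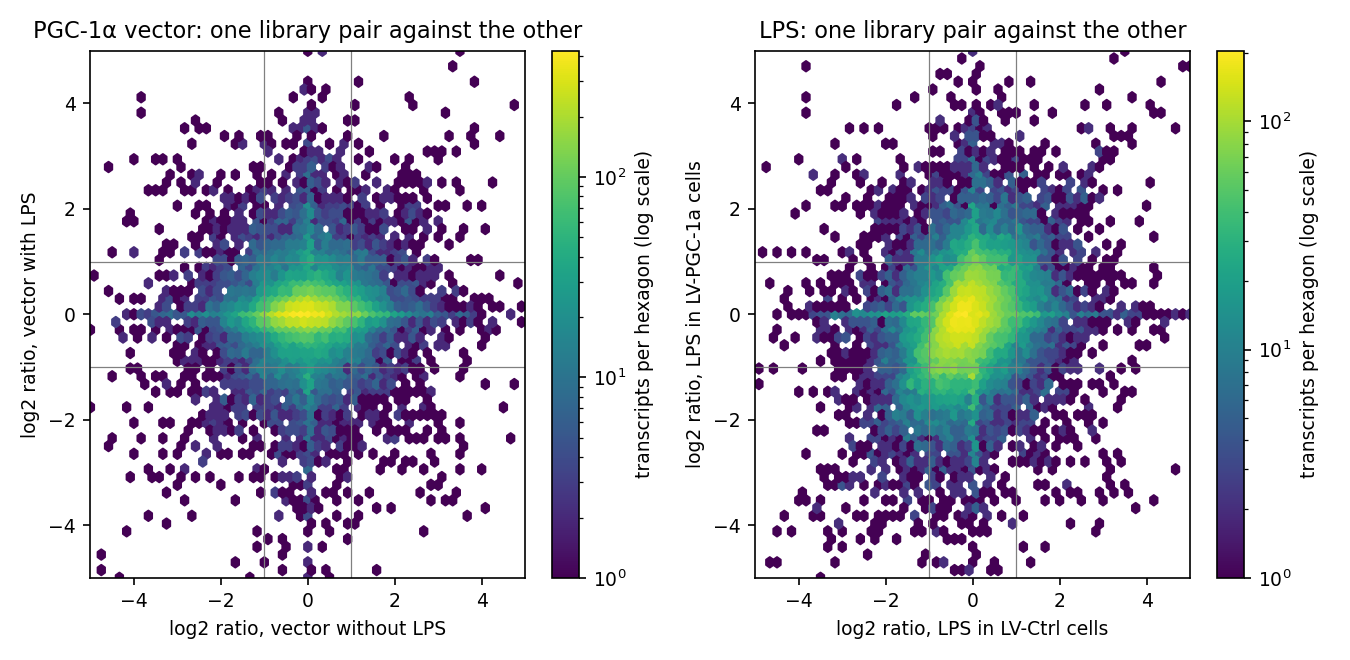
Each hexagon counts transcripts (colour, log scale) by the log2 ratio in one library pair on the x axis and in the other on the y axis, for the PGC-1α vector on the left and LPS on the right, with grey lines at 2-fold and ratios beyond 5 outside the axes. The vector ratios show hardly any diagonal trend (r 0.04), while those for LPS lean along the diagonal (r 0.24).

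The second comparison asks which transcripts differed after LPS. In LV-Ctrl cells 2047 transcripts were 2-fold or more higher and 2676 lower with LPS, or 21.4% of those compared. In LV-PGC-1a cells 2402 were higher and 3430 lower, or 26.5%. In both cell populations 462 transcripts were higher, against 223.0 expected of independent lists, and 897 were lower, against 416.4 expected. Transcripts that went opposite ways were fewer than expected, with 234 higher in LV-Ctrl and lower in LV-PGC-1a cells (318.5 expected) and 218 the reverse (291.6 expected). The 2 log2 ratios correlated across transcripts at r 0.24 and rho 0.29. Over the 525 transcripts with a mean of 100 or more, r was 0.68 and rho 0.54. From a mean of 20 to 100, r was 0.37 and rho 0.52, so ranks hardly showed the rise of r between these bins.

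LPS separated 970 transcripts, 334 higher and 636 lower, which is 3.14 times the 309 of the grouping that follows neither. Among the 525 transcripts with a mean of 100 or more it separated 19. ENSMUST00000021698.12 ranked first among those higher, with values of 371 in LV-Ctrl + LPS and 378 in LV-PGC-1a + LPS; it was listed at 0 in LV-Ctrl and at 0.044 in LV-PGC-1a. Ranked first among those lower, ENSMUST00000108702.7 had 42.2 in LV-Ctrl and 43.3 in LV-PGC-1a and was listed at 0 in both LPS libraries. The size of the smaller log2 ratio lay between 3.71 and 8.51 for the 10 highest-ranked transcripts that were higher and between 3.52 and 5.43 for the 10 that were lower. Of these, 3 of those higher and 5 of those lower were listed at 0 in both libraries of the low side. The excess of lower over higher transcripts depended on scaling: scaling by median ratio raised the median log2 ratio in LV-Ctrl cells by 0.10, gave 2435 higher and 2235 lower there, and gave 587 higher and 710 lower in both populations. After quantile normalization, 2416 were higher and 2323 lower in LV-Ctrl cells, and 583 were higher and 722 lower in both populations.

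**Figure D2:**
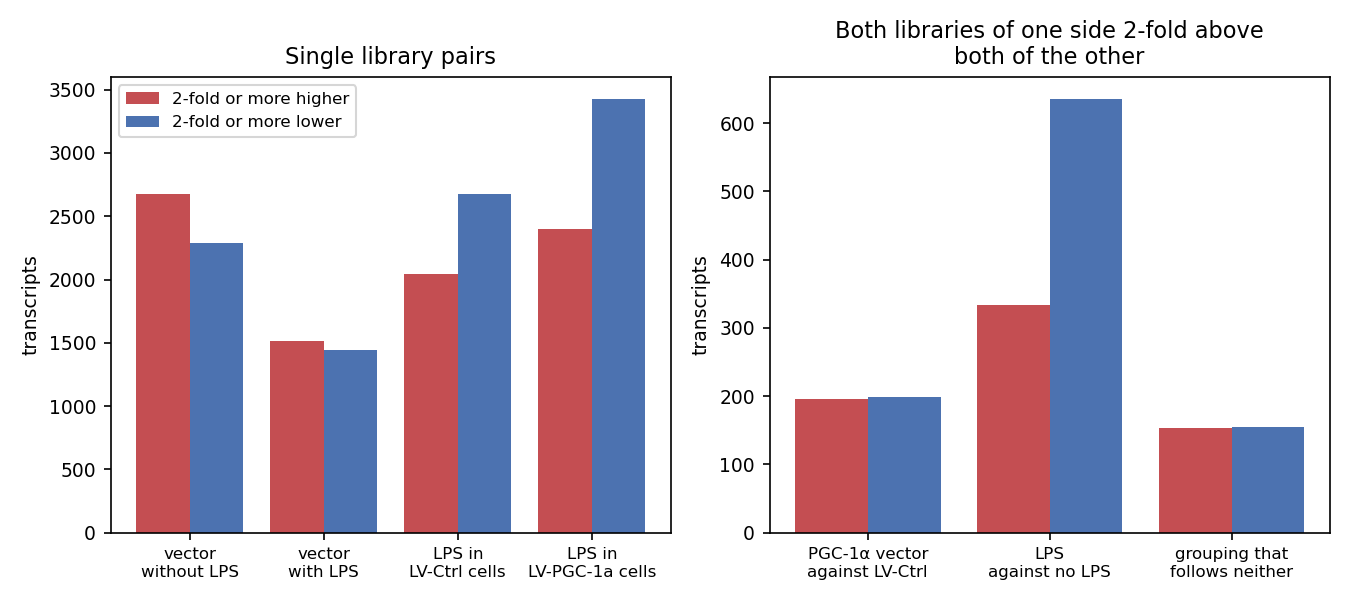
Bars give the number of transcripts 2-fold or more higher (red) or lower (blue), in the 4 single library pairs on the left and for transcripts separated in both libraries of a side on the right. LPS separated 334 and 636, the vector 196 and 199, and the grouping that follows neither 154 and 155, where higher means higher in LV-Ctrl and LV-PGC-1a + LPS.

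**Figure D3:**
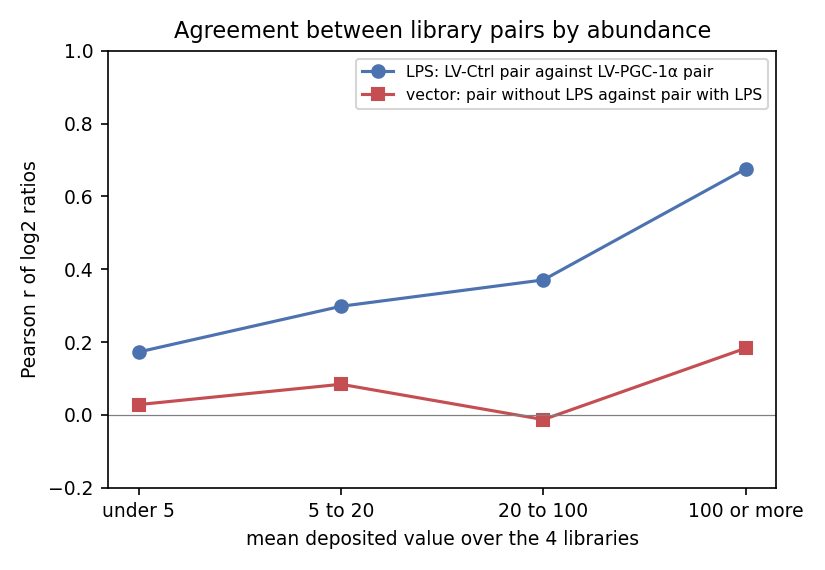
Pearson's r across transcripts between the log2 ratios of 2 library pairs (y axis) is plotted by the mean value over the 4 libraries (x axis), in blue for LPS and in red for the vector. For LPS it was 0.17, 0.30, 0.37 and 0.68 from the lowest to the highest bin, and for the vector 0.03, 0.08, -0.01 and 0.18. Spearman's rho, not plotted, was 0.21, 0.37, 0.52 and 0.54 for LPS, and 0.03, 0.07, 0.11 and 0.19 for the vector.

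The third comparison asks which LPS differences went the other way when the vector was added. There were 628 transcripts higher with LPS in LV-Ctrl cells and lower in LV-PGC-1a + LPS than in LV-Ctrl + LPS, and 587 with the reverse order, 1215 in all. Independent lists would give 134.4 and 184.1. Both ratios use the LV-Ctrl + LPS library, and simulated unchanged libraries gave a mean of 1479 such transcripts, with a range of 1375 to 1586. The observed number was below this range, but the comparison decides nothing. The simulated noise was drawn from the difference of differences, so it holds any real LPS change that the vector reversed. The simulation also gave more 2-fold transcripts between the LPS libraries than were observed, a mean of 4013 against 2964.

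The difference between the vector's ratio with LPS and without LPS was 4-fold or more for 1923 transcripts, of which it was positive for 967 and negative for 956. With 1 library per group this difference has no error estimate. Transcripts 2-fold different with the vector were 1.68 times as many without LPS as with LPS, and this difference was not tested.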

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

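The background grouping was chosen after the correlations were seen, and both tests of the LV-PGC-1a library after the values of the library pairs. The second of those was added after the first had given its result, and noise scaled per library after the first simulation. Rank correlations at high values were added after both correlations were seen.

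Transcripts that went opposite ways in the 2 pairs of a comparison drew attention. With the vector, 224 were higher without LPS and lower with it, and 226 the reverse. With LPS, 234 were higher in LV-Ctrl and lower in LV-PGC-1a cells, and 218 the reverse. These differences were not tested, since each ratio rests on 1 library per group.

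The vector ratios were hardly correlated between the library pairs. Quantile normalization left r at 0.044, which argues against different value distributions. Noise of low transcripts remains open: over the 3513 transcripts with a mean of at least 20, r was -0.001 (bootstrap interval -0.084 to 0.081), under the bound of 0.1 set beforehand, but that bound named Pearson's r alone, and rho was 0.12 (0.09 to 0.16) and rose over the 4 bins of the mean from 0.03 to 0.07, 0.11 and 0.19. A deviation of the LV-PGC-1a library alone remains open, and its 2 tests gave different answers. The smallest SD of a pair with this library was 1.018 times the largest without it (0.999 to 1.035), under the 1.1 set for such a deviation. This test decides little, since its pairs are unlike. It sets LV-PGC-1a and LV-Ctrl (SD 0.964) against LV-Ctrl and LV-PGC-1a + LPS (0.948), which also differ by LPS. Between libraries that differ in the vector alone, the SD was 0.964 without LPS and 0.781 with it. The mean SD of LV-PGC-1a against the LPS libraries was 1.111 times that of LV-Ctrl (1.095 to 1.126). A vector effect that depends on LPS would give the same values, so it and this deviation cannot be told apart with 1 library per group.

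For transcripts separated by the vector, the grouping that follows neither factor gave 0.782 times as many (0.675 to 0.909), and for those separated by LPS 0.319 times as many (0.277 to 0.360). The intervals cover transcripts, not libraries, the ratios follow in part from the correlations already seen, and 4 libraries have only 3 such groupings, so differences between libraries unrelated to vector or LPS remain open for both, beside an effect of the vector or of LPS. Reassignment of reads between transcripts of a gene remains open too: among neighbours by identifier number, opposite changes were 1.156 times as many as same-way changes for the vector and 0.655 times for LPS. This test cannot decide, since how often such neighbours share a gene in mouse is unknown here. Among human transcripts with such a neighbour only 3.48% share its gene. The bound set for the test beforehand therefore decides nothing.

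The 1215 LPS differences that went the other way with the vector may come from the library LV-Ctrl + LPS shared by both ratios. The number lay under the range of simulated unchanged libraries, 1375 to 1586, and under 1429 to 1660 with noise scaled per library. Noise of both simulations was drawn from the difference of differences, so it holds any real LPS change that the vector reversed. The scaled noise also holds any effect of the vector or of LPS. Both simulations overstated the 2-fold transcripts between the LPS libraries, with means of 4013 and 4102 against 2964 observed, and understated those for LPS in LV-Ctrl cells, with 4018 and 4385 against 4723, so they do not decide whether a part of the 1215 goes beyond the shared library.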

How the results depend on the processing

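Quantile normalization, scaling to a total of 1000000, the exclusion of values of 0 and all separated counts were chosen after the data were seen. Dropping the filter could not move a count, since a transcript under 1 in all libraries cannot reach 2-fold on the scale used, so these 11 counts are left out. Of the other 103 recomputed main results, 53 stayed within 1.5 times, or within 0.05 for a correlation, and no correlation changed sign. The balance of higher and lower turned for several counts. For the vector with LPS it turned to 1465 higher and 1530 lower under median-ratio scaling, 1489 and 1540 under quantile normalization, and 2656 and 2696 at a total of 1000000. For LPS in LV-Ctrl cells it turned to 2435 and 2235 under median-ratio scaling and 2416 and 2323 under quantile normalization, and for the vector without LPS to 875 and 933 at a mean of at least 5. The same-way vector counts turned to 258 and 274, 259 and 294, and, at 3-fold, 98 and 104, and were 88 and 88 at a mean of at least 5. With a pseudocount of 0.1, 2-fold transcripts numbered 7584 for the vector without LPS, 5024 with LPS and 7588 for LPS in LV-Ctrl cells; 1347 differed the same way with the vector and 2802 with LPS, r for LPS was 0.187, 2404 went the other way, 4932 passed the difference of differences, and the vector, LPS and neither separated 841, 1987 and 698. With a mean of at least 5, which leaves fewer transcripts, the 4 pairs gave 1808, 831, 1894 and 2260, the same-way counts were 176 and 681, r for LPS was 0.327, 373 went the other way, 681 passed the difference of differences, and 118, 477 and 88 were separated. At 3-fold, a stricter threshold by construction, the pairs gave 1935, 1341, 1767 and 2398, the same-way counts were 202 and 368, 492 went the other way, and 162, 286 and 116 were separated. Without transcripts listed at 0, 1821 differed with the vector with LPS, 342 the same way with the vector, 732 went the other way, 1120 passed the difference of differences, and the vector and neither separated 229 and 166. At a total of 1000000, as TPM would have, the 4 pairs gave 8138, 5352, 7750 and 9208, the same-way counts were 1155 and 2440, 2418 went the other way, 4158 passed the difference of differences, and 794, 1762 and 699 were separated. A pseudocount of 0.1 and this total both lower the weight of the pseudocount against low values, and at this total all 26151 rows passed the filter. How much each of these moved the counts was not tested. Scaling to the same total gave 3081 higher and 1970 lower for the vector without LPS. Of single transcripts and directional counts, 77 moved and 99 did not, again without the counts that dropping the filter could not move. Not run were the choice of rows per gene, since no gene names were used, the table of 2 libraries, which holds the same values, and count-based scaling factors, which need counts. Depth is unknown, so no limit from depth is given.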

Other observations

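The count of transcripts present on one side alone, the ratios of the most abundant transcripts and the fit without interaction were chosen after the data were seen. At 10 or more in both libraries of one side and under 0.5 in both of the other, LPS had 11 transcripts on the LPS side and 9 on the side without. The vector had 4 on the LV-PGC-1a side and 8 on the LV-Ctrl side, and the grouping that follows neither had 7 in all. The 11 transcripts of the LPS side differed between the 2 LPS libraries by a median of 0.12 on the log2 scale, and the 9 of the other side by 0.32 between their libraries. For the vector the medians were 0.71 over 4 and 0.28 over 8 transcripts, and for the grouping that follows neither 0.14 over 5 and 0.12 over 2.

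Of the 10 transcripts with the highest mean, 6 were 1.5-fold or more higher in LV-PGC-1a than in LV-Ctrl, and 4 were 1.5-fold or more higher and 1 lower with LPS in LV-Ctrl cells. With LPS, 0 of the 10 differed 1.5-fold with the vector, and in LV-PGC-1a cells 0 were 1.5-fold higher and 1 lower with LPS. All 10 together took 3.84% of the summed values in LV-Ctrl, 5.78% in LV-PGC-1a, 4.90% in LV-Ctrl + LPS and 5.17% in LV-PGC-1a + LPS, so LV-Ctrl was the lowest. Scaling by median ratio gave 5 and quantile normalization 3 transcripts 1.5-fold or more higher with the vector without LPS, the latter with 2 that were lower. No explanation was tested.

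In a fit of vector and LPS without interaction over the 4 libraries, limma with Benjamini-Hochberg adjustment called 0 of 22045 transcripts for the vector at an adjusted p of 0.05, and 982 had an unadjusted p under 0.05. These 982 are 4.455% of the transcripts. This share cannot be read against the 0.05 of unchanged transcripts, since any real interaction enters the error and would lower the share. For LPS the fit called 2, both higher, and 2714 (12.3%) had an unadjusted p under 0.05. ENSMUST00000021698.12 was the first of these, with a log2 difference of 8.52 and an adjusted p of 0.0103. With the grouping that follows neither as a term, 0 were called beside LPS and 3 beside the vector, and 746 (3.38%) and 546 (2.48%) had an unadjusted p under 0.05. These fits hold the vector or LPS in their residual, so their calls do not compare directly with those for LPS. On simulated libraries the fit for the vector recovered 0% of transcripts set 2-fold higher, 6% at 4-fold, 20% at 8-fold and 72% at 16-fold, so the lack of calls does not show that the vector had no effect. Here the set transcripts were drawn from all 22045. The test of the counting drew them only at a mean of at least 5, so the recoveries do not compare directly.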
